A study of Arabidopsis thaliana with 6 samples.

How the data were processed

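Total RNA from the aerial parts of 6 samples, 3 wild type and 3 epic2, was made into TruSeq version 2 RNA libraries and sequenced as single reads, per the labels' protocols. TopHat, Cufflinks and Cuffdiff and the TAIR10 build are named in the submitters' processing notes, without versions or settings. The labels call the samples biological replicates and do not say whether plants of a genotype were grown apart. How the authors' test modelled the spread between replicates is not given. Its p-values measure at most the spread between these samples, and those of Fisher's exact tests compare genes and measure no spread between samples.

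A single table of 26765 rows was used. The authors deposited 1 FPKM value per group (fragments per kilobase of transcript, scaled to the mapped reads) with the replicates pooled, and how libraries were scaled to each other is not given in the sources used here. Per the file headers the authors' log2 fold change is epic2 over the other group, named silex, and it equalled the log2 ratio of the FPKM values wherever both were above 0. Each row also has the authors' test statistic, p-value and q-value, and the p-value equalled the two-sided normal p of the statistic, so the standard error given beside a log2 fold change is that fold change divided by the statistic. The group silex was taken as wild type by elimination, and if it stands for other plants, each direction given is against those.

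The authors tested 18916 rows. They left out 7783 rows as lacking data and 4 as holding too much, and the test failed in 62. The low FPKM values were inspected and showed no common step from which reads could be recovered, so depth is unknown and no counting interval is given. The precision is instead shown by the implied standard error of the log2 fold change, with a median of 0.16 over tested rows, 0.61 under 1 FPKM and 0.10 at 100 FPKM or more.

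Gene names were joined to the TAIR10.1 RefSeq annotation, whose nuclear coordinates are those of TAIR10. Of 25543 rows with a single name 24982 matched by name, 137 by position and 15 after a symbol turned into a spreadsheet day number was decoded, while 404 locus tags and 5 other names had no match. Rows naming several genes (810) or none (412) entered the overall counts and no gene list. Where a gene had several rows, as 43 genes did, the row with the higher mean FPKM was used. The coordinates printed are the authors' row intervals, which can span overlapping genes. The labels do not state strand, so reads of a gene and of an antisense partner cannot be told apart.

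Genes were called at the authors' q of 0.05 among the rows they tested. Changes were also computed as log2(FPKM + 1), which understates the change of weakly expressed genes. For each of 25 lists (453 genes, 435 with a row of their own) fixed before the data were examined, calls were counted over all tested rows and with the p-values adjusted over the list alone, and two-sided Fisher's exact tests compared rises and falls with all other tested rows, with Benjamini-Hochberg adjustment over lists. The median log2 change of each list was ranked among 10000 random lists matched on mean FPKM in 20 bins. The reference has no class for transposable element genes, so rows were classed as transposon-related where the product or note names a transposon. That definition was chosen after the annotation was seen. Pericentromeric regions were fixed beforehand.

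The 86 genes named in the report's comparisons were chosen by a rule fixed beforehand: the 12 largest rises and 12 largest falls among called rows of a single gene, up to 4 called members of each list by size of change, and PR1, FLC, SDC, FWA, QQS and ROS1. By the same rule the called transposon-related row, which has no gene name, is described too. Other genes named in the closing section were chosen after their values were seen, apart from the clock genes, which are members of a fixed list. The alternatives were a q of 0.01 or 0.10, a minimum mean of 1 FPKM, a 2-fold minimum, Benjamini-Hochberg adjustment over rows of 1 FPKM or more, Bonferroni adjustment, centring on the median, rows of a single gene, and a pseudocount of 0.1 FPKM. Benjamini-Hochberg adjustment over all tested rows of the table was added after seeing the data, as was a scan of the words in annotated products. In that scan each of 453 words of 4 or more letters found in 15 to 500 tested genes was tested for rises and for falls with Fisher's exact test within 17671 tested genes, with Benjamini-Hochberg adjustment over all 906 tests. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. A Benjamini-Hochberg calling step and the list steps were run on simulated data for the comparison of epic2 and wild type. Of 18831 simulated rows 200 changed 2-fold, and 76.5% of these were recovered with 3.2% false calls. The simulated noise had exactly the standard error that the test used, so a low share of false calls was built in. The authors' q was not simulated, so this checks the code and not the calls reported here.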

Results

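RNA of wild type and epic2 plants of Arabidopsis thaliana (accession Col-0) was sequenced from the aerial parts of seedlings aged 17 days, grown with 16 h of light at 24 °C. Each genotype had 3 samples, labelled as biological replicates. The authors deposited 1 FPKM value per group and gene with their own test between the groups, so levels below are the authors' values over 3 samples and carry no spread of their own. The table names its groups silex and epic2. No label uses the name silex. That group was taken as the wild type because the labels give only 2 groups, and each direction below is epic2 against silex. The altered gene in epic2 is not given in the sources used here, so its own level could not be examined. Sequencing depth is unknown.

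The comparison of the genotypes asked which transcripts differ in epic2 plants. On the log2(FPKM + 1) scale the lipid transfer protein gene LTP4 rose most in epic2, and the glycine-rich protein gene GRP9 fell most. Of 18916 tested rows, 3462 (18.3%) passed the authors' q of 0.05, with 1798 higher and 1664 lower in epic2. Changes were mostly small, with a median absolute change of 0.45 among the called rows on the log2(FPKM + 1) scale. Only 307 called rows differed by 2-fold or more on that scale, 94 of them higher and 213 lower. Over the 17456 tested rows with a mean of 1 FPKM or more, the median log2 change was 0.02 and the interquartile range ran from -0.14 to 0.17.

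LTP4 (AT5G59310, chromosome 5, 23925085 to 23925852 in TAIR10) stood at 0.194 FPKM in silex and 17.3 FPKM in epic2, with a log2 fold change of 6.48, a standard error of 1.03 implied by the test statistic and q = 1.19e-08 in the authors' deposited table. Its neighbour LTP3 (AT5G59320, chromosome 5, 23928971 to 23929745) rose from 2.93 to 45.6 FPKM. On chromosome 4, AT4G12490 and AT4G12500, which encode proteins of the same lipid transfer superfamily, rose from 1.17 to 25.6 FPKM and from 0.807 to 7.35 FPKM. Neighbouring genes in each cluster are of 1 family and reads shared between copies were not examined, so the division of reads among them is uncertain. CSLA01, a member of the cellulose synthase-like family, rose from 3.21 to 32.3 FPKM, with a log2 fold change of 3.33 and an implied standard error of 0.16 in the authors' deposited table. AT4G23680, annotated as a polyketide cyclase or lipid transport protein, rose from 13.0 to 112.5 FPKM. AT2G32550, annotated as an Rcd1-like cell differentiation protein, rose from 2.60 to 22.5 FPKM, and AT5G62210, annotated as an embryo-specific protein, rose from 6.19 to 34.6 FPKM. The other genes among the 12 largest rises were AT2G07640, AT5G41780, AT5G17780 and AT3G61920, which reached between 5.48 and 10.7 FPKM in epic2.

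GRP9 (AT2G05440, chromosome 2, 1993082 to 1994166), a glycine-rich protein gene, fell from 12.6 FPKM in silex to 0.686 FPKM in epic2, with a log2 fold change of -4.20, an implied standard error of 0.69 and q = 3.6e-08 in the authors' deposited table. PCC1 (AT3G22231, chromosome 3, 7845823 to 7846605), named for its response to pathogens and the circadian clock, fell from 477.6 to 90.8 FPKM. IAA29, an auxin-induced repressor of auxin signalling, fell from 10.2 to 0.987 FPKM. AGL24, a MADS-box gene that promotes flowering, fell from 33.3 to 6.12 FPKM, and CML41, a calmodulin-like gene, from 103.4 to 18.3 FPKM. PDF1.2, a plant defensin and marker of jasmonate and ethylene signalling, fell from 6.62 to 0.449 FPKM. AT4G11320, annotated as a papain family cysteine protease, fell from 25.1 to 3.06 FPKM. The other genes among the 12 largest falls were AT5G62280, AT2G34655, AT5G22460, AT3G55646 and AT1G76240, which stood between 9.09 and 26.1 FPKM in silex and between 0.747 and 3.88 FPKM in epic2.

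**Figure D1:**
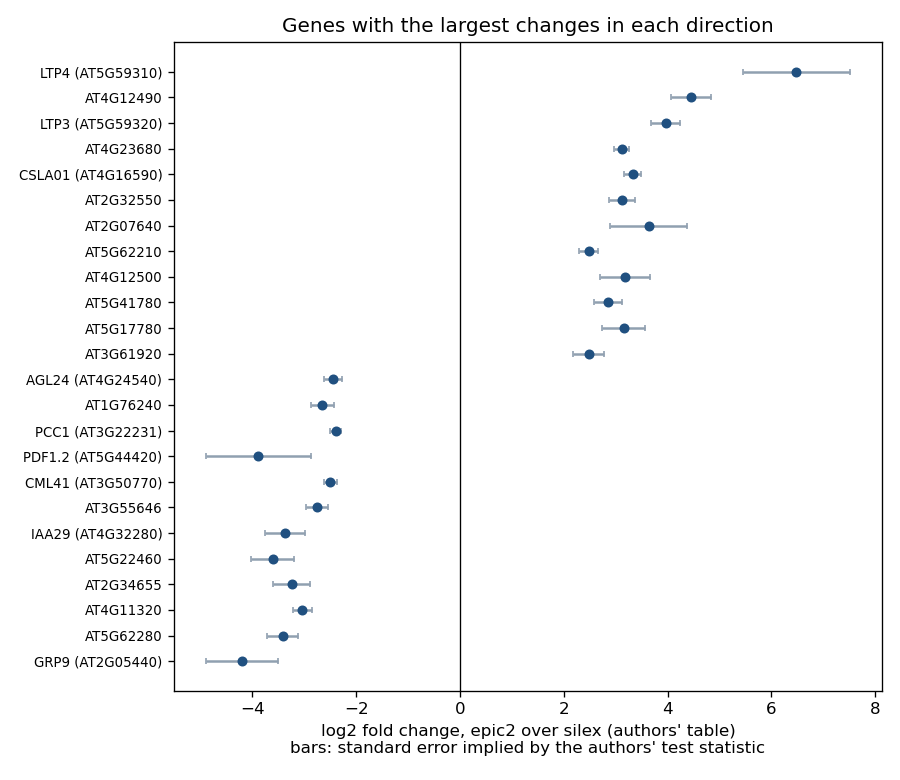
Log2 fold change of epic2 over silex (x axis) for the 12 genes with the largest rise and the 12 with the largest fall on the log2(FPKM + 1) scale (y axis, ordered on that scale), from the authors' deposited table. Points are the fold changes and bars the standard error implied by the authors' test statistic, with LTP4 at 6.48 the highest and GRP9 at -4.20 the lowest of the points.

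Among 25 gene lists fixed before the data were examined, those of flavonoid and anthocyanin synthesis and of the cold and abscisic acid response had more members called higher in epic2 than other genes did. Of 15 tested flavonoid genes 10 rose, 0 fell and 5 did not pass (11 higher and 0 lower adjusted over the list alone), a surplus of rises with an adjusted p of 2.71e-06 (two-sided Fisher's exact test against all other tested rows, Benjamini-Hochberg over the 24 lists with a tested member). F3H, which makes dihydroflavonols, rose from 25.1 to 52.3 FPKM, LDOX, which makes anthocyanidins, from 13.5 to 24.1 FPKM, and FLS1, the flavonol synthase, from 12.4 to 21.2 FPKM. PAP1, a MYB activator of anthocyanin synthesis, rose from 2.75 to 5.37 FPKM. Of 17 cold and abscisic acid genes 7 rose, 3 fell and 7 did not pass (8 higher and 3 lower adjusted over the list alone), and rises were in surplus with an adjusted p of 0.00686 in the same Fisher's exact test. COR15A and COR15B, which protect chloroplast membranes in the cold, rose from 50.8 to 97.6 FPKM and from 3.46 to 7.65 FPKM. The dehydrins COR47 and ERD10 on the same list fell, from 72.0 to 35.8 FPKM and from 59.4 to 36.4 FPKM.

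Genes of auxin response, salicylic acid defence, jasmonate synthesis and response, and glucosinolate metabolism were called lower in epic2 more often than other genes. Of 13 auxin response genes 8 fell, 1 rose and 4 did not pass, with equal counts adjusted over the list alone (Fisher's exact test for falls, adjusted p = 7.28e-05). IAA6 fell from 3.59 to 1.05 FPKM, IAA5 from 6.24 to 3.15 FPKM and GH3.5, which conjugates auxin to amino acids, from 8.46 to 4.44 FPKM. Of 26 salicylic acid and defence genes 10 fell, 2 rose and 14 did not pass (14 lower and 2 higher adjusted over the list alone), with an adjusted p of 0.000462 for falls. The regulator WRKY70 fell from 42.8 to 9.58 FPKM, the cell death regulator ACD6 from 97.9 to 33.5 FPKM, CBP60G, an activator of salicylic acid synthesis, from 5.50 to 1.70 FPKM, and NIMIN1 from 3.97 to 0.855 FPKM. PR1, the usual marker of this pathway, stood at 0.873 and 1.33 FPKM and did not pass (q = 0.490 in the authors' deposited table).

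Of 25 jasmonate genes 9 fell, 4 rose and 12 did not pass, with equal counts adjusted over the list alone and an adjusted p of 0.00137 for falls in Fisher's exact test. At a q of 0.01 the surplus of falls was lost, with 5 members lower and an adjusted p of 0.0852. PDF1.2 fell as given above, and JAZ10, a repressor of jasmonate signalling, fell from 5.04 to 2.04 FPKM. The biosynthetic genes AOC2 and LOX2 rose, from 95.9 to 220.6 FPKM and from 286.4 to 555.2 FPKM. Of 24 glucosinolate genes 8 fell, 2 rose and 14 did not pass (10 lower and 2 higher adjusted over the list alone), with an adjusted p of 0.00431 for falls. CYP79B2 and CYP83B1, enzymes of indole glucosinolate synthesis, had log2 fold changes of -1.02 and -0.67 in the authors' deposited table, with implied standard errors of 0.11 and 0.09, and stood at 10.9 and 71.6 FPKM in epic2. The myrosinase genes TGG1 and TGG2, which break glucosinolates down, fell from 2052 to 1082 FPKM and from 1039 to 568.2 FPKM. Fisher's test takes genes as independent, which genes regulated together are not.

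**Figure D2:**
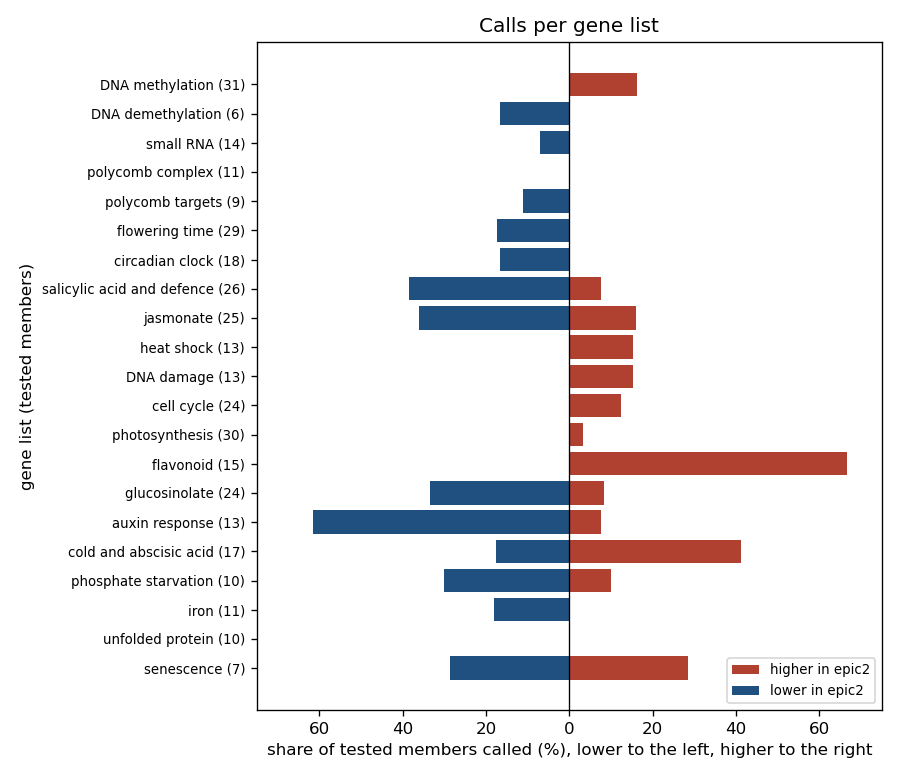
Share of the tested members of each gene list (y axis, with the number of tested members) that was called at a q of 0.05 (x axis, percent), with members lower in epic2 to the left and higher to the right. Lists with fewer than 5 tested members are not drawn, and flavonoid genes (10 of 15 higher) and auxin response genes (8 of 13 lower) show the largest shares.

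The share of called genes in the silencing machinery did not differ past the threshold from that of other genes. Of 31 tested genes of DNA methylation and RNA-directed DNA methylation 5 rose, 0 fell and 26 did not pass, with equal counts adjusted over the list alone and adjusted p-values in Fisher's exact test of 1 for calls in either direction and 0.814 for rises. The median log2 change of this list was 0.09, at percentile 98.8 of 10000 random lists matched on expression level, of which the central 95% lay between -0.11 and 0.07. CLSY1, a chromatin remodeller of RNA-directed DNA methylation, rose from 1.42 to 2.62 FPKM, RDR2 from 2.32 to 3.29 FPKM, DCL3 from 2.47 to 3.28 FPKM and the maintenance methyltransferase MET1 from 7.99 to 10.1 FPKM. The demethylase gene ROS1, the only called member among 6 tested demethylation and anti-silencing genes, fell from 13.9 to 11.7 FPKM, and it did not pass adjusted over the list alone or over the tested rows of the table. Of the known targets of methylation-dependent silencing, QQS fell from 10.9 to 2.56 FPKM, with a log2 fold change of -2.09 and an implied standard error of 0.37 in the authors' deposited table. It was 1 of 2 tested members of that list, and the count was equal adjusted over the list alone. SDC was not tested by the authors at 0.181 and 0.141 FPKM, and FWA was listed at 0 in both groups. Of 14 other small RNA genes AGO7 alone was called, lower at 1.51 against 2.72 FPKM, as it was adjusted over the list alone. None of 11 Polycomb genes was called, with an equal count adjusted over the list alone. Of 9 Polycomb targets only AGL19 was called, listed at 1.01 FPKM in silex and 0 in epic2, and it did not pass adjusted over the list alone or over the tested rows of the table.

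Transposon-related rows were compared with protein-coding genes. Of 18 tested rows whose annotation names a transposon, 1 was called, against 3309 of 17670 protein-coding rows (18.7%), a difference that did not pass Fisher's exact test (p = 0.227). None of the transposon-related rows was called higher (Fisher's exact p = 0.408 against protein-coding rows). As 0 is the lowest possible count, 18 rows were too few for a deficit of rises to pass. The called row overlapped AT4G01525 on chromosome 4 (660806 to 661694) and fell from 6.11 to 3.35 FPKM. Rows without a gene name that overlapped only pseudogenes, with transposon-related rows such as that of AT4G01525 left out, were called in 17 of 132 cases. Of these 9 were higher and 8 lower (Fisher's exact p = 0.0927 for calls against protein-coding rows).

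Called genes were slightly rarer near centromeres in a comparison not matched on expression level. Of 1262 tested protein-coding rows in pericentromeric regions 206 (16.3%) were called, against 3103 of 16408 (18.9%) on the arms (odds ratio 0.84, two-sided Fisher's exact p = 0.0224). Neither the rises alone, at 8.40% and 9.68%, nor the falls alone, at 7.92% and 9.23%, differed past the threshold. The share called rose with level, from 126 of 1460 tested rows under 1 FPKM to 542 of 1390 at 100 FPKM or more. Position and level were therefore not told apart. The only called transposon-related row lay on an arm, where 14 such rows were tested, and none of the 4 pericentromeric ones was called. Across 121 windows of 1 Mb, tested for rises and for falls, 0 of 242 tests passed after adjustment (smallest adjusted p = 0.0855) and 23 had an unadjusted p at or below 0.05 in Fisher's exact test. Organelle-encoded genes were not analysed here.

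Several regulators of flowering and of the circadian clock fell. Of 29 tested flowering time genes 5 fell, 0 rose and 24 did not pass (6 lower and 2 higher adjusted over the list alone), and the surplus of falls did not pass (adjusted p = 0.322, Fisher's exact test). SPL3, which promotes flowering, fell from 13.5 to 3.23 FPKM, and the floral activator FD from 2.47 to 0.977 FPKM. TEM1 and TEM2, which repress flowering, fell from 14.9 to 7.03 FPKM and from 38.5 to 16.0 FPKM. The floral repressor FLC stood at 4.64 FPKM in silex and 7.17 FPKM in epic2 and did not pass (log2 fold change 0.63, q = 0.0520 in the authors' deposited table). Of 18 clock genes 3 fell, 0 rose and 15 did not pass, with equal counts adjusted over the list alone (adjusted p = 0.414 for falls, Fisher's exact test). These were PRR7, from 21.4 to 16.0 FPKM, LNK2, from 406.9 to 316.9 FPKM, and CHE, from 63.4 to 53.1 FPKM.

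In the remaining lists no surplus of rises or falls passed Fisher's exact test after adjustment. Of 24 cell cycle genes 3 rose and 0 fell, among them CYCD3;1, a D-type cyclin, from 19.1 to 31.3 FPKM, CDC20.1 from 16.4 to 22.2 FPKM and KNOLLE, a syntaxin of the cell plate, from 24.9 to 30.8 FPKM. The median log2 change of this list was 0.16, at percentile 99.9 of 10000 random lists matched on expression level. Of 13 DNA damage genes 2 rose and 0 fell, TSO2 from 51.2 to 62.2 FPKM and GMI1 from 1.48 to 2.37 FPKM. Of 13 heat shock genes 2 rose and 0 fell, HSP18.2 from 5.32 to 9.85 FPKM and HSP90.1 from 5.79 to 8.23 FPKM. Of 39 nuclear photosynthesis genes 33 had a row of their own and 30 were tested. Only LHCB4.3 was called, higher at 101.5 against 73.0 FPKM. The photosynthesis genes CAB1, RBCS1A and RCA were among the rows left out as holding too much data, so nothing is known of them here. The median log2 change of the photosynthesis list was -0.05, below all 10000 matched random lists, whose median was 0.17.

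Of 10 phosphate starvation genes 3 fell and 1 rose, with SQD2 falling from 39.3 to 25.9 FPKM and SQD1 rising from 44.6 to 57.8 FPKM, both enzymes of sulfolipid synthesis. SPX1 and AT4 fell from 12.5 to 9.40 FPKM and from 14.0 to 9.64 FPKM, and neither passed when adjusted over the tested rows of the table. Of 11 iron genes 2 fell and 0 rose (3 lower and 1 higher adjusted over the list alone), BHLH38 from 2.46 to 0.794 FPKM and FRO3 from 12.8 to 9.07 FPKM. None of 10 unfolded protein response genes was called. Of 7 senescence genes 2 rose and 2 fell. SAG29 rose from 0.797 to 6.07 FPKM and SAG13 from 2.27 to 5.22 FPKM, while the senescence regulators ORE1 and NAP fell from 3.41 to 0.604 FPKM and from 13.3 to 6.67 FPKM. Of 4 tested root markers 2 rose and 1 fell. PYK10, a beta-glucosidase of roots and of young shoots, fell from 130.9 to 51.8 FPKM, while CASP1, of the root endodermis, and FRO2, a root iron reductase, rose from 0.252 to 1.52 FPKM and from 0.857 to 1.74 FPKM. The 1 tested pollen gene was not called, and no seed gene was tested. Apart from the iron genes, the counts in this group of lists were equal adjusted over the list alone.

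The direction of the calls varied with expression level. Among rows with a mean of 100 FPKM or more 422 were called higher and 120 lower, so that 77.9% of calls were higher. Among rows of 1 to 5 FPKM 181 were called higher and 368 lower (33.0% higher). The median log2 change rose from -0.05 in rows under 1 FPKM to 0.16 (95% bootstrap interval over rows 0.15 to 0.17) in rows of 100 FPKM or more.

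**Figure D3:**
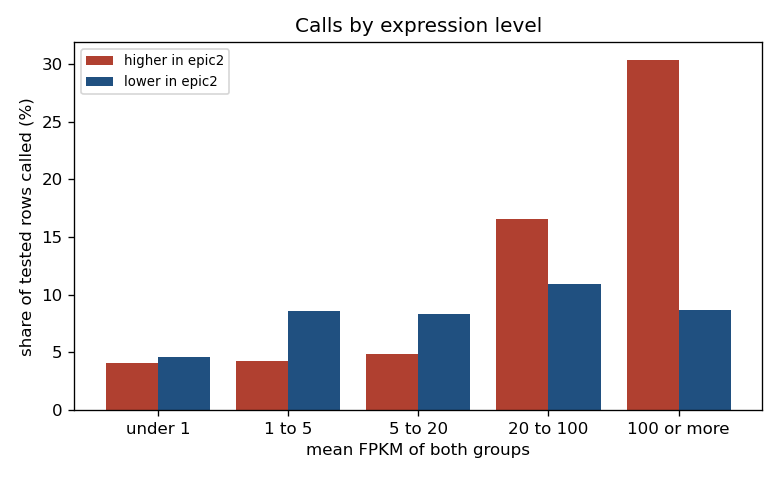
Share of tested rows called higher or lower in epic2 (y axis, percent) by the mean FPKM of both groups (x axis, 5 classes). Rises outnumbered falls in rows of 20 FPKM or more, with 422 rises and 120 falls at 100 FPKM or more, and falls outnumbered rises below 20 FPKM.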

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

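The tests on the time of day, on lists matched by level and on the number of tests behind the q values were chosen after the results were seen, and the other tests before. The rule for the time of day was also made stricter after its value was seen, and a test on GC content took the place of one on ribosomal protein genes, whose result is given among the other observations. SYD, a chromatin remodelling gene whose row the authors' program could not test, stood at 13.3 FPKM in silex and 27.2 FPKM in epic2, a ratio of 2.04. Among 58 rows of 1 FPKM or more in both groups that the authors' program did not test, it was the 1 row at least 2-fold higher in epic2, and PP2-A13, at 7.41 and 3.69 FPKM, was the 1 row at least 2-fold lower. No row left out for lack of data reached 1 FPKM in both groups. This rule was set after the values were seen, and neither difference was tested.

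Calls were mostly higher among strongly expressed genes and mostly lower among weakly expressed ones, with 77.9% of calls higher at 100 FPKM or more and 35.6% under 5 FPKM. A single scaling factor between the groups would shift both classes alike, but their median log2 changes differed by 0.19 (95% bootstrap interval over rows 0.18 to 0.21). Transcript length did not account for the pattern, since within each length class the shares differed by at least 31.6 percentage points. The same held for GC content (at least 32.8 percentage points), although calls were also more often higher in GC-rich transcripts, at 86.7% in the GC-richest and 56.8% in the GC-poorest class among rows of 100 FPKM or more. The genotype and a difference in sample handling or library preparation remain open as possible explanations, and no value per sample was at hand to tell them apart.

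The fall of auxin response genes may in principle come from a drift of weakly expressed genes or from harvest at another time of day. The drift was tested with random lists matched on level, and the auxin list lay at percentile 0 of them, with a median log2 change of -0.47 against a range of -0.14 to 0.17 in the central 95% of random lists. For the time of day, the median log2 change of the morning genes CCA1, LHY and PRR9 minus that of the evening genes TOC1, ELF4, LUX and GI was -0.21. ELF4 was not tested by the authors and none of the others passed, with CCA1 at 186.6 and 177.3 FPKM, but PRR7, LNK2 and CHE fell, so a small shift in harvest time and an effect of the genotype cannot be told apart here.

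The q values in the authors' deposited table were smaller than a Benjamini-Hochberg adjustment of its own p-values gives, with 3462 calls against 3208. A candidate explanation is that the adjustment ran over more tests than the table lists. The ranks implied by p and q came closest to whole numbers for 57014 tests, with a mean distance of 0.052 against 0.17 for the next number that is not its multiple. That is 3.01 times the 18916 tested rows. A run over 3 pairs of groups would give such a number, in which case silex may have been a group apart from a separate wild type, which the table does not settle.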

How the results depend on the processing

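The alternatives were fixed before the data were examined, except the adjustment over all tested rows of the table. The count of called genes moved by over 1.5 times under 3 stricter rules, each of which calls fewer rows by construction, although the falls alone moved by less at a q of 0.01. Of 3462 calls (1798 higher, 1664 lower), a q of 0.01 left 2239 (1119 higher, 1120 lower), a 2-fold minimum left 307 (94 higher, 213 lower) and Bonferroni adjustment left 834 (321 higher, 513 lower). The counts stayed between 3144 and 4284 under a q of 0.10, a minimum of 1 FPKM, adjustment over rows of 1 FPKM or more, rows of a single gene, and adjustment over all tested rows (3208). Centring on the median, a shift of 0.02, and another pseudocount test nothing about the calls, which rest on the authors' q, and leaving out organelle rows removed nothing, as no row was of that kind. The number of lists with a surplus of rises or falls was 6, and 5 at a q of 0.01, where falls among jasmonate genes no longer passed. This was the only change among 142 list results recomputed with other calls or other rows, and the smaller number of calls at that q reduces what the test can find. The odds ratio of calls near centromeres lay between 0.80 and 0.85, and that of transposon-related rows, which did not pass, between 0.26 and 0.42. The median log2 change over expressed genes lay between 0.02 and 0.03. Of the 86 genes named by the rule fixed beforehand, 4 (ROS1, AGL19, AT4 and SPX1) lost their call with adjustment over all tested rows. No paired analysis was possible because the table holds 1 value per group, although the labels number the replicates alike in both groups. For the same reason leaving out replicates, a count model and other splits of the 6 samples were not run. Depth is unknown, and the implied standard error of the log2 fold change, with a median of 0.61 under 1 FPKM, limits what could be detected in weakly expressed genes.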

Other observations

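Each of 453 words found in the annotated products of 15 to 500 tested genes was tested for rises and for falls with two-sided Fisher's exact tests adjusted over all 906 tests. The scan was added after the values were seen, the words overlap in their genes, and those described were chosen from the results. A surplus of rises passed for 26 words and a surplus of falls for 27. Of 342 genes with the word ribosomal 104 rose and 6 fell (Fisher's exact test, adjusted p = 7.65e-25 for rises). The tests of this scan were not matched on expression level, and rises were more frequent among strongly expressed genes. A group of 296 tested ribosomal protein genes, picked after its values were seen, had a median log2 change of 0.20. Random lists matched on level had a median of 0.12, so part of that rise was shared with equally expressed genes. The ribosomal protein group lay at percentile 100 of those lists. Of 15 genes with the word transcriptionally, annotated as plastid transcriptionally active proteins, 11 rose and 1 fell (Fisher's exact test, adjusted p = 1.11e-06), and of 30 with the word tRNA 11 rose and 0 fell (Fisher's exact test, adjusted p = 0.00183). Of 17 genes with the word kinesin, which names motor proteins of microtubules, 6 rose and 1 fell (Fisher's exact test, adjusted p = 0.0477), among them ATK1, from 3.81 to 5.34 FPKM. Without genes annotated as ribosomal proteins 73.7% of the calls at 100 FPKM or more were higher.

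Falls were in surplus for several words from annotations related to the cell wall and for the word receptor-like, though most genes with these words did not pass. Genes with the word pectin include some annotated as inhibitors of pectin methylesterase and not as enzymes. Of 81 genes with the word pectin 23 fell and 4 rose (Fisher's exact test, adjusted p = 3.60e-05), and of 23 with the word xyloglucan 7 fell and 1 rose (Fisher's exact test, adjusted p = 0.0468). XTH6, a xyloglucan endotransglucosylase gene, fell from 208.2 to 105.7 FPKM, while PME5, a pectin methylesterase gene, rose from 48.5 to 109.3 FPKM. Of 37 genes with the word arabinogalactan 14 fell and 1 rose (Fisher's exact test, adjusted p = 9.31e-05). Of 61 SAUR-like genes, a family with auxin-induced members, 13 fell and 0 rose (Fisher's exact test, adjusted p = 0.0417 for falls), with AT5G20820 falling from 4.80 to 0.591 FPKM. Of 87 receptor-like genes 26 fell and 7 rose (Fisher's exact test, adjusted p = 3.30e-06), among them CRK4, a cysteine-rich receptor-like kinase gene, from 9.51 to 2.26 FPKM, while the falls did not pass for the word receptor (16 of 116 lower, adjusted p = 0.381). The falls did not pass for the words expansin (4 of 16 lower, Fisher's exact test, adjusted p = 0.266) and WRKY (9 of 49 lower, adjusted p = 0.238). Among 11 groups picked after their values were seen, whose p-values are therefore too small, a wider group of 19 genes that adds expansin-like members had 7 lower (Fisher's exact test, adjusted p = 0.00144), and the same 49 WRKY genes had an adjusted p of 0.0400 over the 11 groups. The genes named in these observations were chosen after their values were seen, except those already named in the report.

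Genes with large changes lay side by side more often than in shuffled orders. There were 14 pairs of adjacent tested genes that were both called and changed by 2-fold or more in the same direction, against a median of 3 and a maximum of 11 in 10000 shuffles of the changes within chromosomes. Some genes count in more than 1 pair. PCC1 and its neighbours AT3G22235 and AT3G22240 fell together, the neighbours from 1327 to 324.9 FPKM and from 86.8 to 19.8 FPKM. Many of the pairs are of 1 family, and reads shared between copies were not examined. Such neighbours include LTP4 and LTP3, EARLI1, AT4G12490 and AT4G12500, JAL33 and JAL34, AT1G54010 and AT1G54020, and AT4G34770 and AT4G34790. They also include PCC1, AT3G22235 and AT3G22240, of which AT3G22240 is annotated as a PCC1-like protein. JAL33 and JAL34, genes of mannose-binding lectins, fell from 19.8 to 7.32 FPKM and from 22.6 to 8.70 FPKM.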
